A study of Sus scrofa with 2 samples.

How the data were processed

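Single cells of pig endometrium were measured with 10x Genomics 3' chemistry, in which each captured transcript carries a unique molecular identifier (UMI). Per the labels, the tissue came from 2 Yorkshire sows aged 3 years. The embryo loss sow (EL) had an earlier abortion and 3 failed inseminations in a row, and the implantation sow (EIS) was sampled on day 30 after insemination. No gestation day is given for the EL sow, so her stage at sampling is not known here. Each group is 1 sow and 1 library, so sow, pregnancy status, stage and library cannot be told apart. Per the labels' protocols, about 200 mg of tissue was digested with collagenase and a further protease, passed through a fine filter and treated to lyse red cells, steps that can set which cell types were recovered.

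The deposited files hold raw UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes the tool was Cell Ranger 2.1.1, while the matrix header names cellranger 6.1.0, per the file headers. The genome build and annotation are not given in the sources used here. Of 26828 features, 16128 carry an identifier and no gene symbol, and these held 26.7% of EL and 23.0% of EIS UMIs in kept cells. No feature carried a mitochondrial or Y-linked gene symbol, so the planned filter on mitochondrial share and the lists of mitochondrially encoded and Y-linked genes gave no value.

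Barcodes with at least 500 UMIs and at least 300 genes were kept. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, and the top 0.8% per 1000 barcodes was removed, because the automatic threshold marked only 1 EL and 6 EIS barcodes. Both libraries were log-normalised, reduced to 2000 variable genes and 30 principal components without integration, and clustered with leidenalg 0.10.2 on a shared-neighbour graph of 15 neighbours at resolution 1.0. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used. Clusters were named from marker lists of 16 classes. The marker lists, gene lists, named-gene rule and most of the alternative settings were fixed before the data were examined. The score limits for naming were not: the limits of 0.5 (log2) for a class's own markers and 1.2 (log2) for epithelial markers were set after the clusters had been inspected. The minimum of measured markers was raised to 5 after a first pass had named the EL cluster led by CYP26A1 a mast cell cluster. Unnamed clusters held 3527 EL cells (35.8%, exact Clopper-Pearson 95% interval 34.9 to 36.8) and 2324 EIS cells (28.9%, 27.9 to 29.9). Most of the EL part was 1 cluster of 2812 cells with a median of 880.5 UMIs, and the CYP26A1 cluster held 665. An EIS cluster of 837 cells with a median of 750.5 UMIs stayed in the epithelial class because its depth lay just above the limit for leaving such a cluster unnamed.

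Classes with at least 100 kept cells in both libraries were compared. UMIs were summed per library and class and scaled to the same class total (CPM). Levels have exact Poisson intervals, and ratios of EL over EIS have exact conditional intervals. All intervals are at 95% and cover counting error only. Where 1 library had 0 UMIs, the ratio is a bound against 3 UMIs in that library. No test across sows exists with 1 library per group, so no p-value is given. Gene lists were summarised by the median log2 ratio of members with at least 20 UMIs, minus the median of all genes with as many, where at least 5 members were measured. Each median was placed among 10000 random lists of the same size matched on expression in 20 bins, and percentiles below 2.5 or above 97.5 are called outside. The list intervals come from 300 redraws of each gene's UMIs between the libraries.

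The named genes were the 10 largest and 10 smallest ratios per class, among genes with a symbol, at least 100 CPM and 30 UMIs in the higher library, and a level in the class of at least 0.5 of the whole library. Ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes were left out. In ciliated cells 1 gene that met this rule is not reported here, though it stays in the counts. Up to 4 members per list with at least 50 CPM were added, ordered by size of ratio, together with 17 single genes in the class of their highest level. This last part was first run over every class of at least 20 cells, which placed PGR, ESR1, FOXA2 and WNT7A in 29 EL neutrophils on few UMIs. It was then restricted to the 4 compared classes, after those values had been seen. The symbol FGF7 was in no feature used here.

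The computation of the contrast was checked on simulated Poisson counts, drawn for both libraries from 1 shared profile with 200 changed genes per class. The intervals assume such counts, so coverage near 95% follows from the setup. Differences in cluster mix, free RNA and sow were not simulated, so the check does not measure coverage in these data. The intervals held the true ratio for 95.9% of 2490 genes in T or NK cells, 95.7% of 8747 in ciliated cells, 95.6% of 12441 in epithelial cells and 95.3% of 2622 in macrophages. Every gene changed 2-fold or 4-fold came out in the right direction. A 2-fold change was recovered within 0.5 log2 for 89.5%, 95.7%, 96.8% and 88.9% of changed genes in those classes, and a 4-fold change for 86.3%, 94.4%, 95.2% and 89.1%.

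Alternatives covered the gene filter, doublet removal, clustering, scaling (TMM factors from edgeR 4.0.16 in R 4.3.3, median of ratios, and sums without ribosomal protein and haemoglobin genes), weighting cells equally, thinning each cell to 1000 UMIs, removing 10% of each class sum as free RNA, and the minimum of UMIs for lists. A further 5 were chosen after seeing the data: sums without genes over 1% of a library, clusters built without the named genes, the epithelial class without the shallow EIS cluster and the UPK1B cluster, without the CENPF cluster, and with the CYP26A1 cluster added. Figures were drawn with matplotlib 3.10.9.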

Results

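The data comprised 1 endometrial library from a sow with embryo loss (EL) and 1 from a sow with successful implantation at day 30 of pregnancy (EIS). The EL sow's stage at sampling is not given, so every contrast below may also hold a difference in stage. The EL library held 10936 barcodes and 43302286 UMIs, and the EIS library 8848 barcodes and 36069473 UMIs. After the cell filter and doublet removal, 9852 EL cells with a median of 2316 UMIs and 1413 genes and 8054 EIS cells with a median of 2235 UMIs and 997 genes were kept. Genes of uterine secretions dominated the EIS library. SLPI, a protease inhibitor, took 15.3% of its UMIs, ACP5, which encodes the iron-binding secretory protein uteroferrin, 4.02%, and UABP-2, a uteroferrin-associated protein, 3.72%. In the EL library the same genes took 0.029%, 0.006% and under 0.001%. With 1 library per group there is no replicate error, and every interval below covers counting error only.

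The first comparison concerned the cell classes of the EL and EIS libraries. Shares are of all kept cells, so the trophoblast-like cells found only in EIS lower the EIS share of every other class. Epithelial cells made up 46.5% of EL cells (exact Clopper-Pearson 95% interval 45.5 to 47.4, 4577 cells) and 24.96% of EIS cells (24.01 to 25.92, 2010 cells). Ciliated epithelial cells made up 12.3% (11.7 to 13.0) and 3.20% (2.83 to 3.61), a ratio of 3.85 (3.36 to 4.42). Immune cells had the opposite order: T or NK cells were 2.31% of EL and 4.97% of EIS cells, a ratio of 0.466 (0.394 to 0.550), and macrophages, monocytes or dendritic cells 1.27% and 2.89%, a ratio of 0.439 (0.350 to 0.547). Trophoblast-like clusters, the largest of them led by SMPDL3A and PAG6, a pregnancy-associated glycoprotein, held 1763 EIS cells (21.9%, 21.0 to 22.8) and 0 of 9852 EL cells, with a share of up to 0.0374% inside the interval. Stromal fibroblasts were 0.508% of EL and 5.13% of EIS cells, a gap made by 377 cells of a cluster seen only in EIS, while the shared stromal cluster held 0.508% and 0.447% (ratio 1.14, 0.725 to 1.79). Vascular endothelial cells were 0.122% and 4.23%, lymphatic endothelial cells 0.457% and 1.68%, and neutrophils 0.294% and 1.68%. Of the vascular cells, 226 EIS cells lay in a cluster with 0 EL cells. The shared vascular cluster had a ratio of 0.0853 (0.0428 to 0.155). Shares depend on digestion and filtering of the tissue and on the unnamed clusters, which held 35.8% of EL and 28.9% of EIS cells, among them an EIS cluster of 1501 cells with CCL14, C1QA, MRC1 and LYVE1 among its leading genes. Several of these ratios moved with the naming of clusters or with the cells that passed the filter. The epithelial log2 ratio turned from 0.90 to -0.26 at clustering resolution 2.0, where EL clusters led by JPH4, PON3 and JAKMIP1 and an EIS cluster led by DCLK2 were unnamed. The ciliated one moved from 1.94 to 3.42 at a minimum of 200 genes with no UMI minimum, where a shallow cluster led by DLX6 (2256 EL and 10 EIS cells, median 843 UMIs) took that name. The macrophage one moved from -1.19 to -2.62 without doublet removal, where an EIS cluster of 358 cells led by HAVCR1 took that name. At 1000 genes it was -2.63, with 16, 25 and 4 EL cells left in the macrophage clusters against 125 in the main setting. There the ratio of T or NK cells moved from -1.10 to -3.62. The larger T or NK cluster held 25 EL and 189 EIS cells, against 228 and 400 for the class in the main setting. A small cluster led by RHEX, of 5 EL and 54 EIS cells, was also given that name. The stromal ratio moved from -3.34 to between -5.79 and -1.88 in every other setting, where the APOE-led EIS cluster of that name held 104 to 145 cells. In some of these settings a separate EIS cluster was named smooth muscle or pericyte, a class given to no cluster in the main setting. It held 856 EIS cells at a minimum of 200 genes and 547 without doublet removal. The leading genes of the main EIS-only stromal cluster held 2 stromal and 2 smooth muscle markers. With each library clustered on its own the vascular one moved from -5.12 to -1.23, where an EL cluster of 71 cells took that name and 210 EIS cells with PLVAP among their leading genes were named erythroid. The lymphatic one moved there from -1.88 to -4.61. The neutrophil ratio turned from -2.51 to 3.76 at 1000 genes, where the cluster given that name was led by CENPF. The trophoblast share was between 9.17% and 19.2% under 9 of 10 other settings, and from 9.17% to 11.7% a cluster led by SMPDL3A was unnamed.

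**Figure D1:**
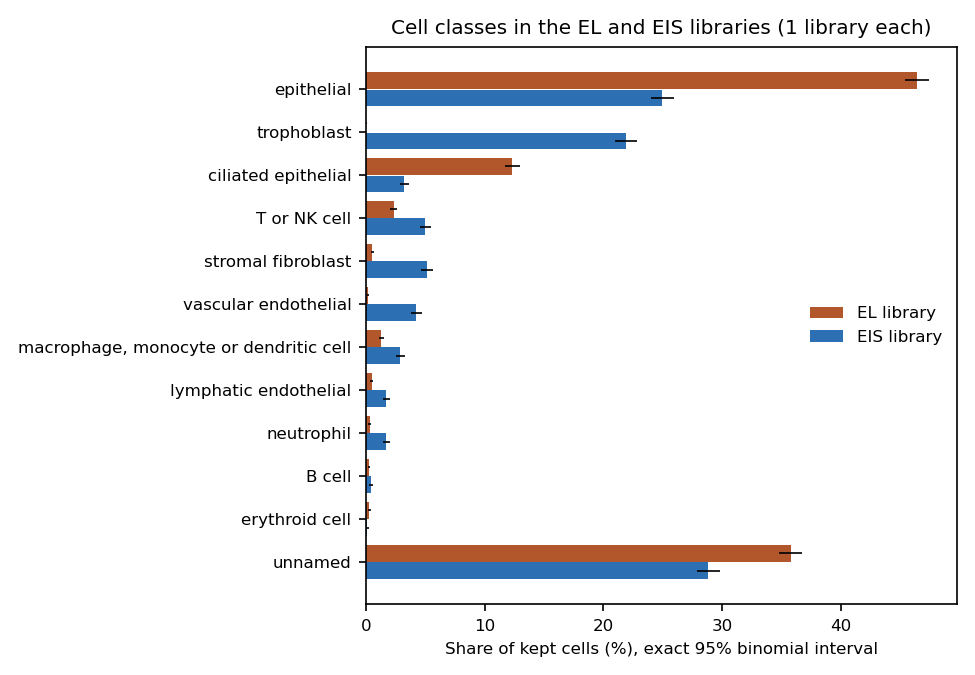
Share of kept cells (%, horizontal axis) per cell class in the EL and EIS libraries, 1 library each, with exact 95% binomial intervals as black lines. Epithelial and ciliated cells took larger shares in EL, and trophoblast cells took 21.9% of the EIS library and none of the EL library.

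Within the epithelial class, the EIS library carried secretory genes that were close to absent from EL. UABP-2 stood at 69473 CPM in EIS (69321 to 69624) and 0.458 in EL (0.198 to 0.903), and SPP1, the adhesion protein osteopontin, at 11910 (11847 to 11973) and 0.802 (0.438 to 1.35). SLPI made up 27.8% and ACP5 7.59% of the EIS epithelial UMIs, against 0.001% and under 0.001% in EL. TIMP2, an inhibitor of matrix metalloproteases, was 690-fold higher in EIS (642 to 742), IGFBP2, a binding protein of insulin-like growth factors, 1291-fold (914 to 1887), and the extracellular superoxide dismutase SOD3 1101-fold (864 to 1427). The sulfotransferase SULT2A1 was at least 2344-fold, the water channel AQP8 at least 1581-fold and the endothelin receptor EDNRB at least 701-fold higher, with 0 UMIs in EL. Higher in EL were CCK, which encodes cholecystokinin, by 1898-fold (525 to 15677), the junctophilin JPH4 by 641-fold (415 to 1050), the monoamine transporter SLC18A2 by 512-fold (200 to 1880) and MGP, the matrix Gla protein, by 192-fold (156 to 238). LYPD1, PON3, JAKMIP1, ISM1, FAM107A and TMEM100 completed this group, from 150-fold to 637-fold higher. The median gene was itself higher in EL by 1.31 on the log2 scale, against 0.15 with TMM factors and 0.38 without the genes over 1% of a library, and relative to that median SPP1 stood at -15.17 and CCK at 9.58. Different clusters supplied the class in the libraries (1, 4, 5, 14 and most of 29 from EL, and 6, 9, 18, 24 and 32 from EIS), and 11 of the 20 genes were among the leading genes of such a cluster. Summed trophoblast markers stood at 78.9 CPM in EL and 554 CPM in EIS, erythroid markers at 2.81 and 75.4, lymphatic markers at 3.32 and 38.8 and neutrophil markers at 6.24 and 34.9. Plasma cell markers stood at 175 and 435 and smooth muscle markers at 65.5 and 155. Ciliated markers stood at 150 and 55.2 and vascular markers at 132 and 58.0. Mast cell markers stood at 392 and 44.9, mesothelial markers at 27.55 and 0.603 and B cell markers at 10.88 and 2.59. SLC18A2, itself a listed mast cell marker, stood at 176 CPM in EL and 0.345 CPM in EIS.

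Of 23 gene lists with a median in epithelial cells, 14 lay below and 1 above the central range of random lists. Folds of single members are not adjusted for the median gene, which was itself higher in EL by 1.31 (log2). BIRC3, HIF1A and HMGB2 were higher in EL but lay below that median gene. In the uterine secretion list 17 of 18 measured members lay below the median gene, with a median of -4.43 (-4.86 to -3.86), below all random lists. Prostaglandin synthesis and transport had a median of -4.55 (-4.95 to -4.42), with 10 of 11 members below the median gene. HPGD, which inactivates prostaglandins, was 33.7-fold higher in EIS (30.1 to 37.9), the prostaglandin E synthase PTGES 18.1-fold (14.7 to 22.6), CBR1 8.85-fold (8.18 to 9.59) and the receptor PTGER2 2.87-fold (2.50 to 3.31). Nutrient and ion transport had a median of -2.61 (-2.77 to -2.20), with the fatty acid transporter SLC27A2 28.9-fold, the transferrin receptor TFRC 25.4-fold and CA2 21.9-fold higher in EIS, while the water and glycerol channel AQP3 was 130-fold higher in EL (115 to 148). The steroid list had a median of -1.33 (-1.46 to -1.01), yet its members with the largest ratios were higher in EL. These were HSD11B2, which inactivates cortisol, by 54.8-fold, FKBP5 by 23.3-fold, the oestrogen receptor ESR1 by 16.7-fold (15.0 to 18.7) and the progesterone receptor PGR by 12.6-fold (9.92 to 16.3). Inflammatory cytokines had a median of -3.34, with IL6 661-fold (183 to 5470), CXCL16 4.18-fold and TNFAIP3 3.98-fold higher in EIS and BIRC3 2.39-fold higher in EL. Angiogenesis had a median of -1.82, with ADM 10.95-fold and VEGFA 7.998-fold higher in EIS, HIF1A 1.67-fold higher in EL (a log2 ratio turned to -0.42 with TMM factors) and VEGFB 1.42-fold higher in EIS. Complement (-3.05), matrix proteases (-2.33), TGF beta and growth factors (-2.34), glycolysis (-0.96), immediate early genes (-1.30), the unfolded protein response (-1.06), implantation adhesion (-1.31) and collagens (-3.36) also lay below all genes. The unadjusted medians of glycolysis (0.34) and the unfolded protein response (0.24) were higher in EL and that of immediate early genes was 0.00473. That of implantation adhesion was -0.0047, with 7 members higher in EL and 8 in EIS. The steroid list had an unadjusted median of -0.024, with 10 members higher in each library. The cell cycle list lay above all genes by 0.93 (0.52 to 1.52, percentile 99.8), which rested on a cluster of 57 EL and 3 EIS cells led by CENPF and CCNB1. Without that cluster, a setting chosen after seeing the data, the median turned to -0.49, and STMN1, 13.2-fold higher in EL, kept a log2 ratio of 3.70 while HMGB2, 2.29-fold higher, fell to 0.51. CENPF-led clusters also left the class at 1000 genes (median -1.02) and at resolution 2.0 (HMGB2 at -0.75). The steroid median turned to 0.71 in thinned cells, and the collagen median to 1.46 with 10% free RNA removed. That removal can take a gene of low level in the class to 0, so the collagen value may rest on bounds. With the EL cluster led by CYP26A1 in the class, HPGD, PTGES and CXCL16 were higher in EL, at log2 ratios of 0.26, 0.77 and 0.0464, while the median of the prostaglandin list stayed below that of all genes.

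In ciliated epithelial cells the differences were far smaller, and 1 cluster held most of the class in both libraries. ID1, ID3 and ID4, which restrain basic helix-loop-helix transcription factors, were 4.19-fold (3.73 to 4.74), 2.62-fold and 2.60-fold higher in EL, with the retinaldehyde dehydrogenase ALDH1A1 at 3.75-fold (3.15 to 4.49), the sterol enzyme ACAT2 at 2.91-fold and VEGFB at 2.65-fold. APOBEC1, CDH6 and DPEP2 lay between 2.75-fold and 3.15-fold. Metallothioneins, which bind zinc and copper, were higher in EIS: MT1A by 20.5-fold (18.0 to 23.5), MT1D by 18.1-fold (16.4 to 20.0) and MT2A by 7.61-fold (7.09 to 8.18). FXYD2, a regulator of the sodium pump, was 6.497-fold, SAL1, a lipocalin, 5.73-fold, YBX3 4.02-fold, the pyruvate dehydrogenase kinase PDK4 3.85-fold, ZUP1 3.70-fold, SOCS3 3.28-fold and SLC28A3 3.19-fold higher in EIS. ALDH1A1 stood at 0.549 of its level over all EL cells, and MT1A, MT1D, MT2A, SAL1 and SOCS3 at 0.599 to 0.955 of theirs over all EIS cells. Stromal markers summed to 60.8 CPM in EL and 268 CPM in EIS, trophoblast markers to 96.3 and 185 and erythroid markers to 1.47 and 15.4. SAL1 had no direction when each library was clustered on its own (log2 ratio 0.02).

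Of 22 lists in ciliated cells, 5 lay below and 2 above the random range. Nuclear genes of oxidative phosphorylation differed by a small amount, with 24 of 27 below the median gene and a median of -0.21 (-0.30 to -0.20, percentile 0.02). ATP5ME was 1.74-fold, NDUFA4 1.53-fold, ATP5PO 1.49-fold and NDUFA3 1.42-fold higher in EIS. The WNT and epithelial list lay above all genes by 0.43 (0.18 to 0.68, percentile 99.7): SPDEF, a transcription factor of secretory cells, was 25.3-fold higher (11.6 to 69.3) at 0.135 of its level over all EL cells, LEF1 1.35-fold higher, and LGR4 and FOXA2 lay within counting error of equality. The inflammatory list stood at 0.31 (-0.03 to 0.40, percentile 99.1), with NFKBIA 1.79-fold, CXCL2 1.62-fold and TNFAIP3 1.34-fold higher in EL and SOD2 1.28-fold higher in EIS, and it turned to -0.36 without doublet removal and -0.24 with no minimum of UMIs. Secretions (-0.89), collagens (-2.09), matrix proteases (-0.46) and complement (-0.51) lay below all genes, and ACP5, RBP4, TIMP2 and COL3A1 in EIS ciliated cells stood at 0.0238 to 0.123 of their level over all EIS cells. The secretion median turned to 1.28 with 10% free RNA removed. That removal took ACP5 in EIS ciliated cells, at 0.301% of UMIs against 4.02% over the library, to 0. The turned median therefore rests in part on bounds and gives no direction.

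In T or NK cells the cytotoxic effector list was the 1 list above the random range. KLRB1, the receptor CD161, was 5.68-fold higher in EL (3.56 to 9.30), the chemokine XCL1 5.03-fold (4.18 to 6.07), the adhesion receptor CD96 3.43-fold (2.29 to 5.18) and LY6D 8.34-fold (5.12 to 14.1), with the interferon-induced genes MX1 and EIF2AK2 at 2.51-fold each. The interferon response list itself lay inside the random range, with a median of 0.086 relative to all genes (percentile 72.4). FBXO39, BACH1, CCDC50 and MDFIC were 2.77-fold to 4.11-fold higher. Higher in EIS were SOCS3 by 2.96-fold (1.75 to 5.34), the interleukin 7 receptor IL7R by 2.82-fold (1.93 to 4.26), PCBP2 by 2.68-fold, KLF2, which controls lymphocyte recirculation, by 2.67-fold (2.36 to 3.02), S1PR1, a receptor for exit from tissue, by 2.07-fold (1.35 to 3.28) and CD8A by 1.97-fold (1.55 to 2.53). LSP1, OSBPL8, ZFP36 and RASA3 were 1.98-fold to 2.06-fold higher. Of 16 lists, cytotoxic effectors lay above all random lists, with 9 of 12 members above the median gene and a median of 0.64 (0.30 to 0.76), including CCL5 at 1.93-fold and the death ligand FASLG at 1.80-fold (1.22 to 2.62). Immediate early genes lay below all random lists, with 15 of 18 members below the median gene and a median of -0.52 (-0.68 to -0.41), MYC among them at 1.96-fold higher in EIS (1.04 to 4.00). Secretions (-4.72), collagens (-2.80) and implantation adhesion (-0.46, turned to 0.33 with no low-count filter) lay below all genes as well, and SLPI, TIMP2 and COL3A1 in EIS T or NK cells stood at 0.0565 to 0.0933 of their level over all EIS cells. The class's own markers summed to 18364 CPM in EL and 11376 CPM in EIS, stromal markers to 81.1 and 548, erythroid markers to 3.24 and 85.2, ciliated markers to 127 and 50.3 and mast cell markers to 38.9 and 7.74. Members of the cytotoxic list such as NKG7, PRF1, KLRB1, XCL1 and CCL5 are also markers by which the class was named. Random lists were matched on expression alone. The cytotoxic list median therefore cannot be told apart from the higher level of the class's own markers in EL. BACH1 stood at 0.948 of its level over all EL cells and SOCS3 at 0.723 of its level over all EIS cells. These sums rest on 228 EL and 400 EIS cells that sit in clusters of different weight. Cluster 16, with XCL1 and IL7R among its leading genes, held 134 EL and 106 EIS cells (1.36% and 1.32% of each library), and cluster 12 held 94 and 294. The class gave no value at a minimum of 1000 genes.

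In macrophages, monocytes or dendritic cells LYVE1, the hyaluronan receptor, was 25.1-fold higher in EIS (14.3 to 48.7), and the mannose receptor MRC1 14.8-fold (9.28 to 25.02). The chemokine CCL14 was 16.4-fold (8.55 to 36.0), the endocytic adaptor DAB2 8.24-fold (6.44 to 10.7) and SPP1 31.6-fold (25.5 to 39.8) higher. The lectin CD209 was at least 16.1-fold higher, with 0 UMIs in EL, and COLEC12, CD200R1L, RGL1 and HOMER3 were 5.54-fold to 40.5-fold higher. In EL, S100A4 was 6.54-fold higher (5.28 to 8.13), CPSF6 4.82-fold (4.25 to 5.47), the lipid antigen presenting CD1.1 4.08-fold (2.61 to 6.42), LY6D 18.7-fold (9.11 to 43.1), SNX10 3.04-fold (2.44 to 3.79) and the proton pump subunit ATP6V0D2 145-fold (24.8 to 5868). EMB, ARNT, NECAP1 and PYGL were 3.14-fold to 19.4-fold higher, and ATP6V0D2 and PYGL stood at only 0.568 and 0.642 of their level over all EL cells. Of 21 lists, 7 lay below the random range and none above. Immediate early genes had a median of -0.68 (-0.75 to -0.45, percentile 0.01). KLF2 was 3.48-fold, SOCS3 3.31-fold and NR4A1 1.82-fold higher in EIS. In contrast CCN2, the member with the largest ratio, went the other way at 20.6-fold higher in EL (9.70 to 50.3) and 0.267 of its level over all EL cells. The inflammatory list had a median of -0.33 (-0.50 to -0.12, percentile 1.39), with TNF 2.68-fold, CCL2 2.58-fold, CCL4 2.01-fold and CXCL2 1.60-fold higher in EIS, the last turned to a log2 ratio of 0.18 without doublet removal, where the class took in the EIS cluster led by HAVCR1. TGF beta and growth factors (-0.85), with IGF1 3.30-fold higher in EIS (1.44 to 9.33), prostaglandins (-0.67), with HPGD 4.08-fold and PTGS1 2.25-fold higher in EIS, apoptosis (-0.43), with BBC3 2.79-fold higher in EIS and MDM2 1.82-fold higher in EL, collagens (-2.03) and secretions (-0.41) lay below all genes too. Epithelial markers summed to 988 CPM in EL and 401 CPM in EIS macrophages, ciliated markers to 338 and 43.9, lymphatic markers to 39.3 and 914, stromal markers to 78.5 and 377 and mast cell markers to 112 and 9.35. LYVE1, itself a listed lymphatic marker, stood at 36.2 CPM in EL and 909 CPM in EIS, close to the whole of that lymphatic sum. The class rests on 125 EL and 233 EIS cells. The libraries differ in cluster mix, with 113 EL and 120 EIS cells in cluster 17, 7 and 58 in cluster 27 and 5 and 55 in cluster 28, where LYVE1, MRC1 and CCL14 were among the leading genes. The secretion median turned to 0.55 with 10% free RNA removed. That removal took ACP5 in EIS macrophages, at 0.271% of UMIs against 4.02% over the library, to 0. The turned median therefore rests in part on bounds and gives no direction.

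**Figure D2:**
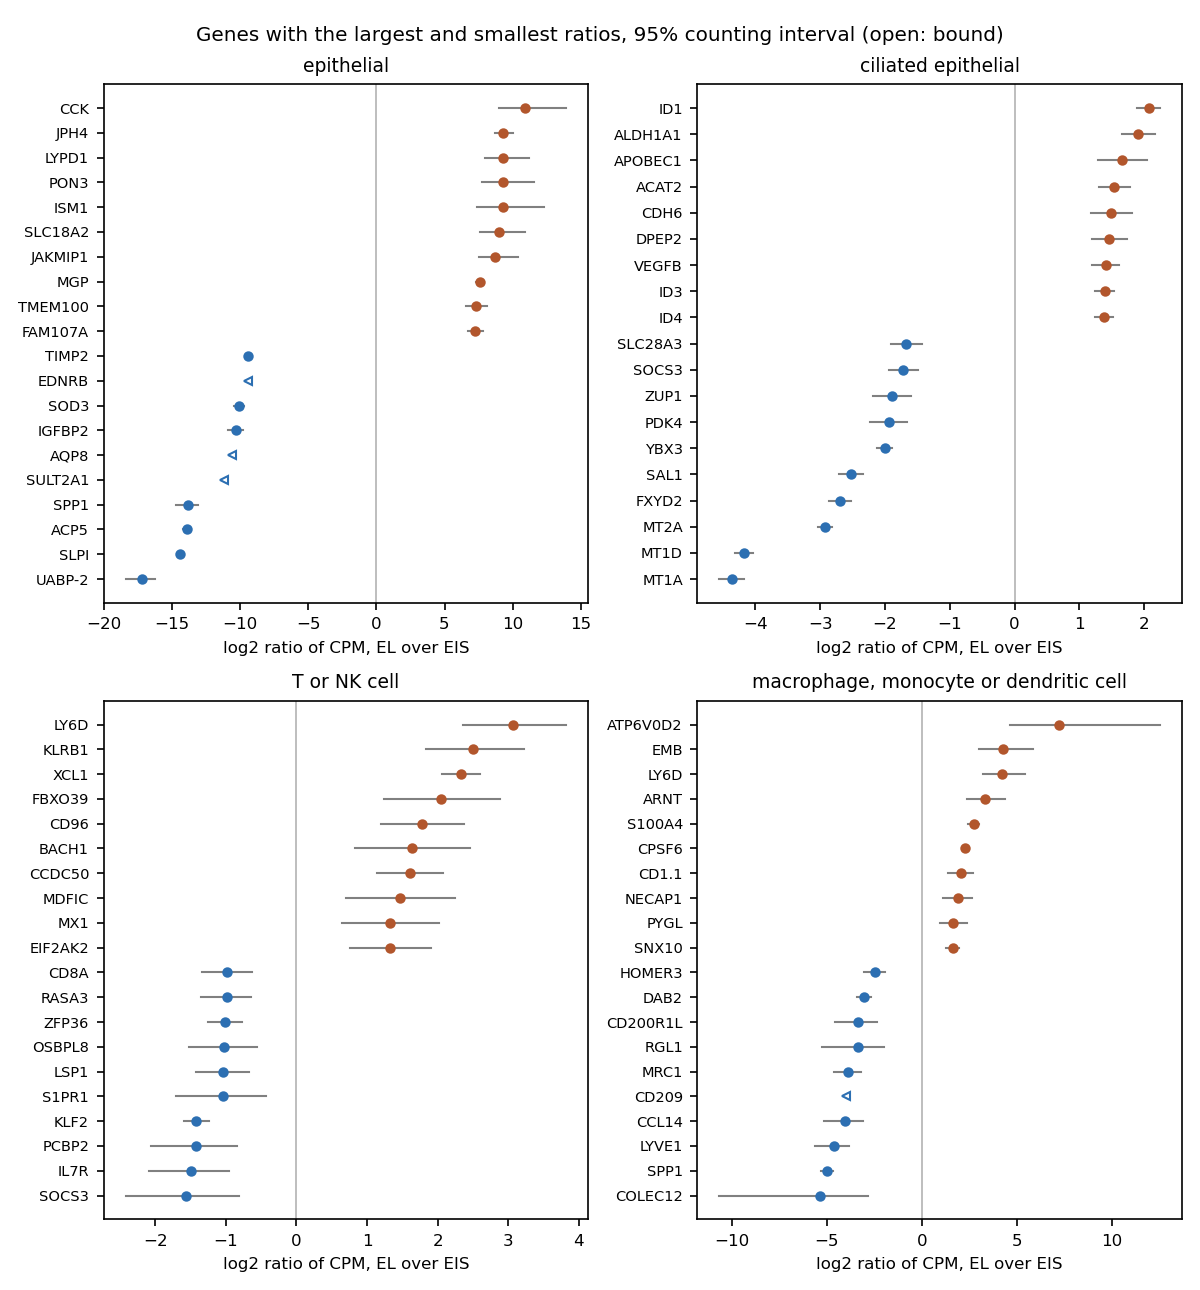
Log2 ratio of CPM, EL over EIS (horizontal axis), of the reported genes with the largest and smallest ratios in each of 4 cell classes, with 95% counting intervals as grey lines and bounds as open triangles. The epithelial ratios span from -17.21 for UABP-2 to 10.89 for CCK, and those of T or NK cells from -1.56 to 3.06.

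**Figure D3:**
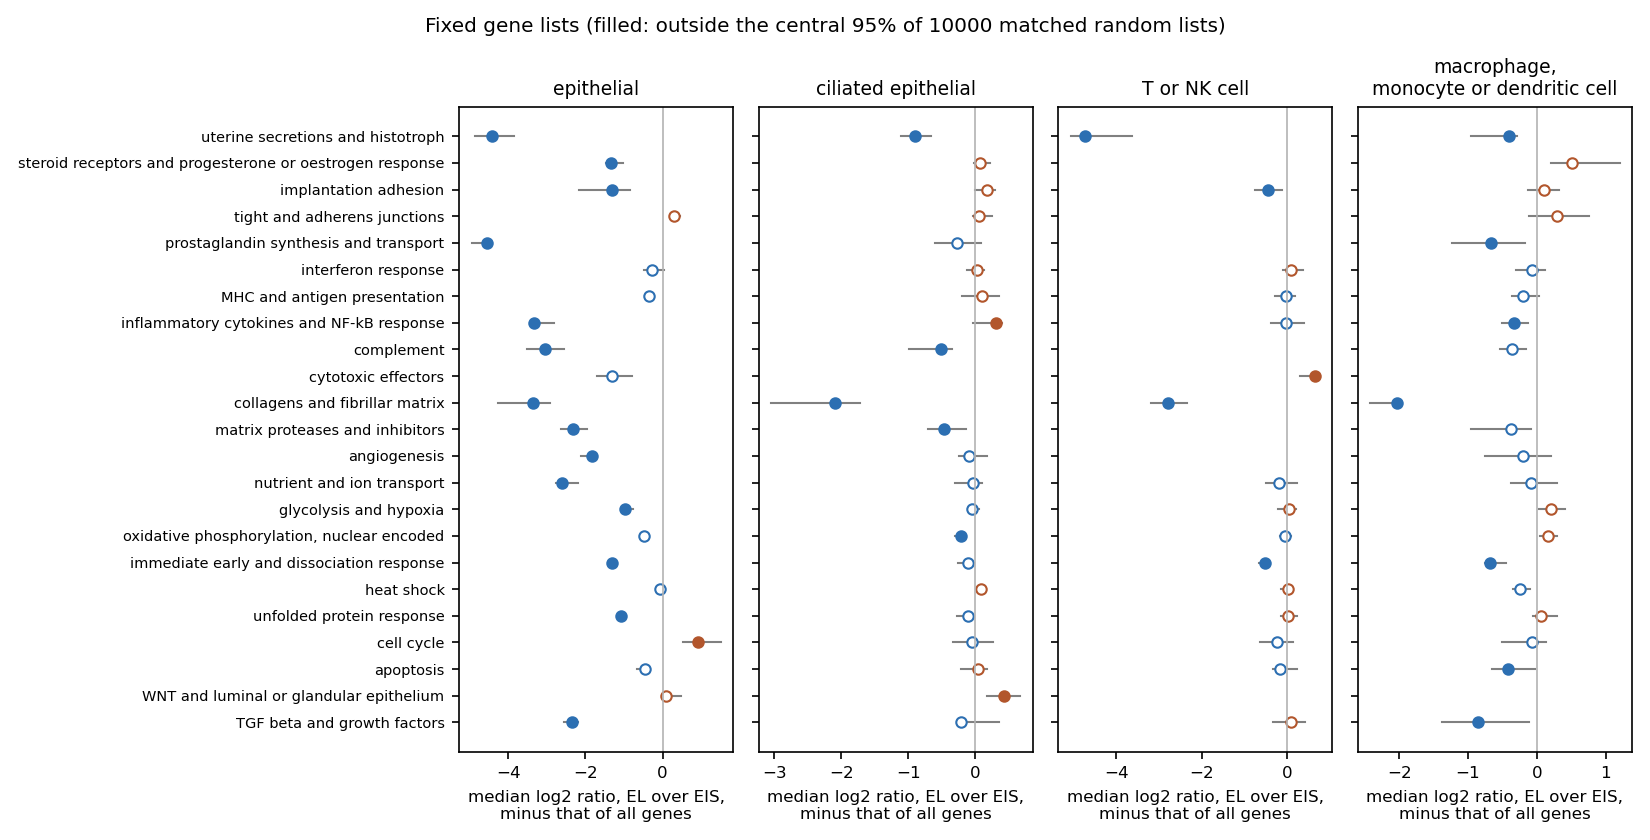
Median log2 ratio, EL over EIS, of each fixed gene list minus the median of all genes (horizontal axis), per cell class, with counting intervals as grey lines and filled points outside the central 95% of 10000 matched random lists. Epithelial cells had 15 of 23 lists outside, ciliated cells 7 of 22, macrophages 7 of 21 and T or NK cells 5 of 16.

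Among single genes chosen for their part in pig pregnancy, the leukaemia inhibitory factor gene LIF stood at 52.3 CPM in EIS epithelial cells (48.2 to 56.7) and 0.057 in EL (0.001 to 0.319), and the retinol carrier RBP4 at 10358 CPM and 374 CPM. FOXA2, a regulator of gland formation, was 4.11-fold higher in EL (3.78 to 4.47), or 0.73 on the log2 scale relative to the median gene. WNT7A was 4.62-fold higher in EIS, but its log2 ratio turned to 3.48 in favour of EL with the CYP26A1 cluster in the class. STC1 (63 UMIs in EIS, 4 in EL) and the prostaglandin transporter SLCO2A1 (48 and 2) were low in both libraries, with ratios of 0.0422 (0.0112 to 0.113) and 0.0277 (0.00326 to 0.106). In macrophages VEGFA (ratio 1.19, 0.817 to 1.70) and the cyclooxygenase PTGS2 (0.601, 0.244 to 1.29) did not differ beyond counting error, and HAND2 had 4 UMIs in epithelial cells. Outside the 4 compared classes, HAND2 had 228 UMIs in the EIS-only stromal cluster. Among the 4 compared classes MUC1 was highest in ciliated cells, at 7.96 CPM in EL and 18.8 CPM in EIS, a ratio of 0.425 (0.272 to 0.673).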

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

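The predictions for doublets, for a like amount of free RNA per droplet, for expression by each class and for tissue handling were written after the results they concern had been seen, and the other 3 before.

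Signals outside the comparisons, above the limit that 0 allows, were 1763 trophoblast-like cells in the EIS library and 36 EIS cells of an epithelial cluster with UPK1B among its leading genes. Features with an identifier and no symbol took 23.0% of EIS UMIs and 26.7% of EL UMIs, so that share is not particular to EIS.

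The first pattern is the trophoblast-like clusters together with a stromal cluster of 377 cells seen only in EIS. Conceptus tissue sampled with the endometrium could account for both. In that stromal cluster the summed level of PGR, ESR1 and HOXA10 was 0.221 (0.180 to 0.273) of that in EIS cells of the shared cluster. HOXA11, also in the sum as predicted, was not used here. The prediction as written asked only for a ratio under 0.25, which the value met. Its interval holds 0.25, however, so the test was taken as undecided for the stromal cluster. It did not examine the trophoblast-like clusters, which held 1763 EIS cells and 0 EL cells. PAG6, GATA3 and CYP11A1 were among the leading genes of the larger of those clusters. Doublets of maternal cells are excluded as the whole cause, because 21.9% of kept EIS cells (21.0 to 22.8) lay in trophoblast clusters against 7.08% of doublets expected, and the lowest share under any setting was 9.17%. No biological explanation can be separated from the sow, since each group is 1 sow.

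The second pattern is SLPI, ACP5 and UABP-2 UMIs in every EIS class. Free RNA from gland cells was not decided: the ratio of ACP5 to SLPI differed 1.68-fold between the highest and lowest of 8 classes, from 24.04 to 40.50 ACP5 UMIs per 100 of SLPI, above the limit of 1.5 and below that of 3, and 1.29-fold without the 33 B cells. A like amount in every droplet is excluded, as mean SLPI UMIs per cell differed 24.9-fold, from 20.3 in T or NK cells to 504 in trophoblast cells. For expression by the cells of each class, SLPI ranged 10.4-fold, from 0.976% to 10.2% of UMIs. Under the criterion first written this would have fitted, but that criterion was changed after the value was seen to require the ACP5 to SLPI ratio to differ over 3-fold too, and under the changed one it is undecided.

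The third pattern is the lower level of immediate early genes in EL T or NK cells and macrophages. Free RNA of other EIS cells is excluded as the whole cause: the median member stood at 2.16 times its level over all EIS cells in T or NK cells and 1.79 times in macrophages. Tissue handling that differed between the libraries could lower such genes in every class. In ciliated cells the list lay at percentile 9.20 of random lists, outside neither limit, so the test did not decide. In epithelial cells the same list lay at percentile 0.01, with a median of -1.30 relative to all genes and 0.00473 unadjusted, which leaves handling open.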

How the results depend on the processing

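Which list members were recomputed was limited, after values were seen, to lists outside the central range, the 20 genes at the floor in both libraries (12 in T or NK cells, 1 ciliated, 2 epithelial, 5 macrophage) were left without a ratio with free RNA removed after their values were seen, the stromal, vascular, lymphatic and neutrophil shares were recomputed only after they had been seen, and 5 alternatives were chosen after seeing the data. Of 3168 values for 194 genes, 2427 stayed within their interval, 699 moved and 42 reversed; of 1123 list medians 908, 205 and 10; of 90 shares 48, 40 and 2. Over all members of all lists, 4824 of 6065 values for 381 genes stayed, 1159 moved and 82 reversed, most often without doublet removal (13). The count of named genes in the stated direction hardly responds: all 64 values lay within 1.5 times of 20. Log2 ratios of shares, against -1.10 for T or NK, 1.94 for ciliated, 0.90 for epithelial cells and -1.19 for macrophages, and trophoblast percent of EIS, against 21.9, were, in that order where they moved: at least 200 genes and no UMI minimum, ciliated 3.42, epithelial 0.80, trophoblast 19.2; at least 1000 genes, T or NK -3.62, ciliated 1.55, epithelial 3.06, macrophage -2.63, trophoblast 10.00, with median UMIs of 4172 in EL and 4645 in EIS; no doublet removal, epithelial 0.39, macrophage -2.62, trophoblast 18.6; automatic doublet threshold, trophoblast 9.17; resolution 2.0, ciliated 2.56, epithelial -0.26, macrophage -1.81, trophoblast 9.97; centred per library, epithelial 0.69, trophoblast 9.96; own clustering, T or NK -0.83, ciliated 2.37, epithelial 1.01, trophoblast 9.56; 4000 variable genes, epithelial 0.58, trophoblast 11.6; without the named genes, trophoblast 11.7. For stromal cells, against -3.34, they were, in the same order, -2.05, -5.79, -2.09, -2.09, -2.09 (resolution 2.0), -2.12, -1.88, -2.05 and -2.11, and -2.10 at resolution 0.5. Vascular cells, against -5.12, were at -3.55 (resolution 0.5), -3.44 (centred) and -1.23 (own clustering), lymphatic cells, against -1.88, at -2.51 (1000 genes) and -4.61 (own clustering), and neutrophils, against -2.51, at 3.76 (1000 genes) and -1.80 (own clustering). Reversed log2 ratios in epithelial cells were, at 1000 genes, HMGB2 -0.0697; without doublet removal, NR4A1 -0.65, CCN2 -0.15, ATF4 -0.16; at resolution 2.0, DCN -0.0549, NR4A1 -1.25, CCN2 -0.43, ATF4 -0.44, HMGB2 -0.75; with the CYP26A1 cluster, LGALS3 0.71, HPGD 0.26, PTGES 0.77, CXCL16 0.0464, CTSL 0.80, WNT7A 3.48; with TMM, CD9 -0.13, HIF1A -0.42, CCN2 -0.0702, XBP1 -0.18, CALR -0.68, ATF4 -0.71; with median of ratios, CD9 -0.17, HIF1A -0.46, CCN2 -0.11, XBP1 -0.21, CALR -0.72, ATF4 -0.74, HMGB2 -0.0014; without ribosomal protein genes, CTSL 0.0708; by mean of cells, ATF4 -0.14; with free RNA removed, COL3A1 2.91, CTSL 0.0804; without abundant genes, HIF1A -0.19, CALR -0.45, ATF4 -0.48. In other classes they were LGALS1 0.21 in T or NK cells and ACP5 1.60, RBP4 1.49 and CTSL 0.0376 in ciliated cells with free RNA removed, SAL1 0.0183 with own clustering and CFD 0.22 by mean of cells in ciliated cells, and CXCL2 0.18 in macrophages without doublet removal. List medians reversed for implantation adhesion in T or NK cells (0.33) and the inflammatory list in ciliated cells (-0.24) with no low-count filter, the latter also without doublet removal (-0.36); for secretions in ciliated cells (1.28) and macrophages (0.55), epithelial collagens (1.46) and the epithelial steroid list (0.0075) with free RNA removed; and for the steroid list in thinned cells (0.71) and the cell cycle at 1000 genes (-1.02) and without the CENPF cluster of 60 cells (-0.49). At 1000 genes a CENPF-led cluster was named neutrophil, at resolution 2.0 both such clusters were unnamed, and without doublet removal 358 EIS cells led by HAVCR1 were named macrophage. Values reversed with free RNA removed can be bounds against 3 UMIs, as for ACP5 in ciliated cells, and then give no direction. Other causes were not tested. T or NK cells and macrophages gave no value at 1000 genes, nor macrophages when thinned, which left out 468 EL and 761 EIS epithelial cells. No paired analysis was possible because each group holds 1 library, and the filter on mitochondrial share was not run.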

Other observations

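The genes named in this part were chosen after their values were seen, and no further test was run.

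Stromal fibroblasts of the EIS library fell into a cluster found only there and a cluster shared with EL. The EIS-only cluster carried HAND1 at 206 CPM (189 to 224), the imprinted genes MEST at 510 CPM (484 to 538), DLK1 at 108 CPM (96.1 to 121) and PEG10 at 263 CPM (244 to 283), and ACTA2 at 1830 CPM (1779 to 1881). EIS cells of the shared cluster had 0 UMIs of HAND1, MEST, DLK1 and ACTA2 and 16.2 CPM of PEG10. They carried more APOD (9496 against 14.9 CPM), NR2F2 (521 against 5.44), ESR1 (121 against 9.79), PGR (80.8 against 3.26) and HOXA10 (323 against 103), while HAND2 went the other way (16.2 against 82.7). In EL cells of the shared cluster APOD stood at 154 CPM. The shared cluster holds 50 EL and 36 EIS cells.

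An unnamed EL cluster of 665 cells, with a median of 12995 UMIs, was led by CYP26A1, an enzyme that degrades retinoic acid, with HDC, TSPO, SLC28A3 and WNT7A among its leading genes, and held no EIS cell. Its markers scored as epithelial, and it stayed unnamed because HDC is a listed mast cell marker. An unnamed EIS cluster of 422 cells held no EL cell. In EL macrophages ACP5 took 0.486% of UMIs (0.462 to 0.510) while SLPI took 0.002%, and in EIS macrophages ACP5 took 0.271% (0.261 to 0.281).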
